A study of Homo sapiens with 8 samples.

How the data were processed

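RNA from 8 cultures of TE8 and HSC-2 cells was measured on 8 one-colour (Cy3) human expression arrays, 1 array for each of the 8 groups. Per the labels' protocols, cells were incubated for 24 h with the reagents at the doses given, and nothing in the labels names a second culture of any group. The TE8 sample labelled DFEX was taken as DFX because the label of the HSC-2 DFX sample uses both spellings. Per the file headers, the arrays were read and processed with Agilent Feature Extraction 11.0.1.1, and all 8 came from 1 slide and 1 scan. TE8 filled column 1 of the slide and HSC-2 column 2, so line and column cannot be told apart, while comparisons within a line stay within a column.

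The values are spot intensities on a linear scale, as deposited: the processed signal, from which the scanner software had already taken its background, per the file headers, with its own error estimate and flags for background, saturation and outliers. No scaling between arrays had been applied in these files. Of 60901 spots that are not controls, those of a probe were averaged in log2, which gave 58201 probes. A set of 300 probes is spotted 10 times, and their copies gave a median SD of 0.047 to 0.057 (log2) within an array. In all, 27 probes with no copy free of an outlier flag on some array were left out, 14 of them named. A processed signal is well above background by the software's own flag, which held for 46.9% to 55.3% of probes per array. The number of arrays, 1 per group, limits the precision.

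The files hold no gene names. RefSeq accessions, without versions, named 31104 probes (22439 symbols) through a gene table of assembly GRCh38.p14, of which 22433 genes entered the analysis. The file headers name build hg19 for the array design, so the table served for names alone and no coordinates are given. The other 27097 probes had no match and stay unnamed. A gene was represented by its brightest probe over the arrays. For 29 genes the brightest probe was never well above background while another probe was, and these were kept with the brightest.

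The main scale is log2 of the processed signal minus the array's 75th percentile. A gene was judged in a comparison when well above background on at least 1 of the 2 arrays, and called at 2-fold or more. Where an array was not well above background its value was replaced by the higher of its own signal and the lowest signal well above background on that array, which gives a bound ("at least N-fold"), set to 0 where it would change sign. Across lines a gene with any array of 1 side not well above background is given as such a bound on the difference of means. List medians within a line used bounds too. The fits across lines, camera included, used the signals as measured, also those not well above background. A p-value beside a bound therefore belongs to the measured difference and does not test the bound. A list median was set against 10000 random lists of the same size drawn within 20 bins of mean signal, for lists with at least 5 judged genes.

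Across lines, limma (3.58.1, R 4.3.3; lmFit and eBayes) was fitted with cell line as a block: on the 6 arrays of control, cisplatin and DFX (2 residual degrees of freedom), and on all 8 arrays with the chelators as a class (4 residual degrees of freedom). The lines act as replicates, and differences between lines, or between chelators, count as spread, so p-values cover these arrays only. Genes well above background on at least 2 arrays of the fit were tested, a filter set before the fit was seen but not written down in advance. P values were adjusted by the method of Benjamini and Hochberg at 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 25 lists and 4 contrasts (100 tests), with an estimated correlation and with fry as alternatives. With an estimated correlation, camera takes its p from the residual degrees of freedom of the fit (2 or 4). Little can then pass after adjustment over 100 tests, so a lost call does not show that a list was unchanged. The direction in camera differed from the sign of the median in a few lists with adjusted p from 0.504 to 0.988, among them mitosis for cisplatin (median 0.03, down).

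The 25 lists, fixed with the design before the data were examined, were iron uptake and storage, HIF targets, glycolysis, p53 targets, DNA repair, DNA replication, mitosis, stemness, ATF4 and amino acid stress, unfolded protein response, NRF2 targets, metallothioneins and zinc, interferon response, NF-kB and inflammation, immediate early genes, cholesterol synthesis, respiratory chain, heat shock, squamous differentiation, basal keratinocyte, EMT, histone genes, ribosome biogenesis, fibroblast markers, and leukocyte and endothelial markers. Some genes stand in more than 1 list, such as STC2, VEGFA and SLC7A11. Genes were named by a rule fixed at the same time: in each of the 6 comparisons the 8 highest and 8 lowest genes measured on both arrays, up to 4 members of each list with the largest difference, and NANOG, POU5F1, SOX2, TFRC, FTH1, CDKN1A, MDM2, NDRG1, VEGFA and CA9. In each contrast across lines the 8 genes with the smallest adjusted p per direction were named, or the 3 with the smallest p where fewer than 3 passed, and between chelators the 5 highest and 5 lowest. Of the genes this rule selects, 1 is not reported here.

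Correlations of log2 differences are Pearson's r over 13853 genes, for 15 pairs of comparisons. For pairs with a shared control, 100 sets of unchanged arrays were drawn with the residual spread of the fit across lines. That spread includes real differences between lines, so it can overstate chance.

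The alternatives were quantile normalization, scaling on the median of 24377 probes well above background on all arrays, scaling on 7 of the 10 spike-in probes (each probe's median copy, averaged over probes), normexp background correction with an offset of 50, the mean of a gene's probes, stricter and no filters on dim probes, a variance trend and leaving out each array. The files used hold no mean signal, so normexp was run on the median signal and the median background. The spike-in alternative was planned as a median over spike-in probes. It was run as the mean over probes well above background on all arrays. Scripts were tested on simulated data. For DFX across lines (16954 genes), limma recovered 0% of 200 genes changed by 1 and 65.5% of those changed by 2 (log2), with 11.3 false calls per draw in the latter and 0.1 where nothing changed. For DFX in TE8 (16846 genes) the 2-fold rule recovered 95.5% of 200 genes changed by 2, with 0 false calls, and 7 of 200 unchanged lists were shifted. Both simulated arrays carried spot error alone and no spread between cultures, so the 0 false calls say nothing about differences between cultures. The unchanged lists were random genes set against random draws of the same genes, so a small share shifted was fixed by the rule. The 7 lists therefore give no false rate for genes that move together or for spread between cultures. A list moved by 0.5 had an unadjusted camera p under 0.05 in 10 of 10 draws with either correlation. With the preset, 12 of 240 tests of unchanged lists fell under 0.05. Genes were drawn independently of each other, so these draws cannot show whether the preset correlation holds for the arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the comparisons within a line and the plots.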

Results

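Gene expression was profiled on 8 one-colour microarrays, each hybridised with RNA from a human cancer cell line after 24 h of culture. TE8 is an oesophageal squamous cell carcinoma line and HSC-2 an oral squamous cell carcinoma line. TE8 was sampled as an untreated control and after cisplatin (CDDP, 10 µM), DFX (50 µM) or SP10 (5 µg/ml). HSC-2 was sampled as an untreated control and after cisplatin (10 µM), DFX (50 µM) or SP6 (100 µg/ml). Cisplatin is a platinum drug that cross-links DNA. DFX, SP6 and SP10 are iron chelators in the design of the study, and SP6 and SP10 are known here by code name only. Each of the 8 groups held 1 array, so no comparison within a line has a replicate check or a p-value. Of 58201 probes, 46.9% (HSC-2 SP6) to 55.3% (TE8 control) were well above background, and no probe was saturated. Copies of a probe on the same array varied with a median SD of 0.047 to 0.057 (log2), and the scanner software put the median error of a spot at 0.145 (log2). These errors cover the array only, not the spread between cultures.

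The design asks what an iron chelator changes in each line, beside cisplatin as a reference drug. Within a line, a gene was called higher or lower at 2-fold or more, and all differences are log2 values, treated minus control of the same line unless another pair is named. A gene list fixed before the data were examined is called shifted when its median lay outside the central 95% of 10000 random lists of the same size and signal. That percentile describes these arrays and is not a p-value.

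In TE8, DFX gave the widest response of that line. Genes of the hypoxia response (HIF targets) were higher, 30 of 37 by at least 2-fold and 0 lower, with a median of 2.27. CA9, a carbonic anhydrase of hypoxic tumours, was higher by 4.85, STC2 by 4.69, the nuclear receptor RORA by 4.40 and EGLN3, an oxygen-sensing prolyl hydroxylase, by 4.29. VEGFA (2.65) and NDRG1 (2.57) moved with them. In glycolysis 10 of 18 genes were higher (median 1.03), led by the hexokinase HK2 (4.99) and the glucose transporter SLC2A3 (3.99). Genes of terminal squamous differentiation held the highest values of the array. SPRR2A, a precursor of the cornified envelope, was higher by 8.79, SPRR2E by 8.24, SPRR2C by 7.70 and LCE3D by 7.38, and 18 of 29 listed genes were higher against 2 lower (median 1.70). The chemokine receptor CXCR4 (7.32) and the transcriptional repressor PRDM1 (5.24) were also among the 8 highest, with SPRR2F (6.21) and LCE3E (5.47).

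Stress genes were higher in TE8 with DFX too. In the ATF4 and amino acid stress list 18 of 27 genes were higher and 0 lower (median 1.89), among them CHAC1 (4.31), ATF3 (3.97) and TRIB3 (3.62). Immediate early genes were higher in 16 of 20 cases (median 1.91), with the phosphatases DUSP5 (3.58) and DUSP1 (2.95) in front, followed by IER5 (2.70) and DUSP6 (2.51). The p53 target list was shifted higher with 15 of 35 genes higher and 2 lower, and CDKN1A, the cell cycle inhibitor p21, stood at 3.39. NF-kB and inflammation genes (12 of 21 higher, 3 lower, median 1.11) included BIRC3 (2.79) and TNFAIP3 (2.68). Cholesterol synthesis (11 of 24 higher, median 0.89), the unfolded protein response (5 of 20 higher, DNAJB9 at 2.73), NRF2 targets (6 of 23 higher, OSGIN1 at 2.80), interferon response (6 of 24 higher, 1 lower, MX2 at 2.37) and stemness genes (3 of 16 higher, 3 lower) were shifted higher as lists. Histone genes went apart inside their list: 10 of 18 were higher, such as H2BC5 (2.32), and 4 lower, such as H1-5 (-2.84).

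The lowest gene in TE8 with DFX was KRT15 (-5.83), a keratin of basal epithelial cells, and other low genes were S100A3 (-5.02), MGP (-5.00), RAB26 (-4.56), KANK4 (-4.46), NKAIN4 (-4.40) and SALL4 (-4.35), a transcription factor of pluripotent cells. TP63, a regulator of basal keratinocytes, stood at -2.59, although the basal keratinocyte list as a whole was shifted higher (median 0.60, 5 of 15 higher and 4 lower). The lists of DNA repair (median -0.42, 3 of 32 lower), DNA replication (-0.26, 5 of 33 lower, PRIM1 at -1.68) and ribosome biogenesis (-0.20, 2 of 26 lower, UTP20 at -2.06) were shifted lower. Mitosis (median 0.15), EMT (0.29), heat shock (0.41), metallothioneins and zinc (0.35), the respiratory chain (-0.02) and iron uptake and storage (0.10) were not shifted. Of the iron genes, the transferrin receptor TFRC stood at 1.38 and the ferritin heavy chain FTH1 at 0.10. NANOG was at -1.39, POU5F1 at -0.91 and SOX2 at 1.84. Collagen and stroma genes that mark fibroblasts were shifted lower (median -1.31, 3 of 6 lower, FAP at -3.96), and HBB, a marker of blood, was at 5.16.

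In all, 2166 genes were higher and 1993 lower of 17076 judged in TE8 with DFX, 534 of them known only as a bound because one array was not well above background. With spike-in scaling the median of all genes moved by -0.56 and 17.5% of the calls were higher, in place of 52.1%. The lists of p53 targets, stemness, the unfolded protein response, NRF2 targets and interferon response then had medians below 0, while their place against random lists stayed higher.

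In HSC-2, DFX gave higher HIF targets again: 34 of 37 HIF targets were higher by at least 2-fold and 0 lower (median 1.78). RORA (4.46), RIMKLA (4.11), ANGPTL4 (3.64) and NRN1 (3.22) led them, NDRG1 stood at 1.99 and VEGFA at 1.44, and CA9 was at least 3.83-fold higher. Glycolysis was shifted higher with 4 of 18 genes higher and 1 lower, with ENO2 at 4.08 and the phosphofructokinase PFKM at -2.04. Genes of cell division were lower. Of 31 mitosis genes 30 were lower (median -2.26), among them the kinesin KIF20A (-4.23), HMMR (-3.41), cyclin A (CCNA2, -3.35) and DLGAP5 (-3.23). DNA replication followed with 25 of 33 lower (median -1.38; UHRF1 -2.94, PRIM1 -2.71, ORC1 -2.68), and DNA repair with 18 of 32 lower (median -1.07; FANCD2 -2.27, BLM -2.14).

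Interferon response genes were lower in HSC-2 with DFX, 15 of 22 with 1 higher (median -1.62), such as OAS2 (-3.54), OASL (-2.88) and IFIT3 (-2.48). Ribosome biogenesis (16 of 26 lower, median -1.09), the respiratory chain (4 of 35 lower, median -0.62) and metallothioneins and zinc (2 of 11 lower, median -0.80) were shifted lower as well. Squamous differentiation was shifted higher with 16 of 31 genes higher and 1 lower (median 1.23). Among its genes measured on both arrays LCE3D (5.82) led, with CDSN (4.17), which holds corneocytes together, while the highest value of the list was a bound (6.15). ATF4 and amino acid stress (9 of 27 higher, 1 lower, ATF3 at 3.32), immediate early genes (7 of 19 higher, 1 lower, DUSP1 at 3.10), basal keratinocyte genes (6 of 15 higher, 1 lower, with KRT15 at -2.49), EMT (9 of 22 higher, 3 lower, SNAI1 at 2.78 and ZEB1 at 2.74) and histone genes (10 of 18 higher, 5 lower, H4C3 at -2.92) were shifted higher. The p53 targets (8 of 34 higher, 3 lower, CDKN1A at 2.33) and cholesterol synthesis (2 of 24 higher, SC5D at 2.05) lay just above their random lists. NF-kB and inflammation genes split, 6 higher and 8 lower of 23, with PTGS2 at 2.89 and CXCL1 at -2.79. Iron uptake and storage (median -0.14), stemness (-0.02), NRF2 targets (-0.18), heat shock (-0.26) and the unfolded protein response (0.03) were not shifted. TFRC was at 0.35, FTH1 at 0.35, POU5F1 at 1.78 and SOX2 at -2.57, and NANOG was not well above background.

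Single genes were ranked among those measured on both arrays. The highest single genes in HSC-2 with DFX after LCE3D were GAST (5.76), the hormone gastrin, IGFBP1 (5.50), IRAG1 (5.35), IQCN (5.09), ZP1 (4.94), IGFBP3 (4.88) and PAG1 (4.81). The lowest were ALDH3A1 (-5.40), H1-1 (-4.62), PIF1 (-4.56), CDCA7 (-4.40), KIF20A (-4.23), CYP1A1 (-3.88), POLE2 (-3.74) and NNMT (-3.64). Of 15717 genes judged 1935 were higher and 2130 lower, 519 as bounds. With spike-in scaling the median of all genes moved by -0.50, 18.2% of calls were higher in place of 47.6%, and the medians of p53 targets, cholesterol synthesis and EMT turned negative while staying above their random lists.

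With cell line as a block, limma tested the mean difference of DFX from control over TE8 and HSC-2, not a change in each line. It found 171 genes higher and 71 lower of 16954 at an adjusted p under 0.05 (2145 and 2034 at an unadjusted p under 0.05), a balance that turned to 253 higher and 1206 lower with spike-in scaling. SPINK6, a skin protease inhibitor, was at least 44.95-fold higher and RFPL4AL1 at least 45.07-fold higher, each not well above background in either control. CDSN rose by 4.32 (SE 0.25), LCE3D by 6.60 (SE 0.43), RORA by 4.43 (SE 0.27), MARCHF3, a ubiquitin ligase, by 4.27 (SE 0.29), while LCE2C was at least 8.17-fold and PKIB, an inhibitor of protein kinase A, at least 5.85-fold higher. Genes that fell included CLXN (-3.59, SE 0.24), the mitochondrial dehydrogenase HSD17B8 (-3.43, SE 0.25), the glycosyltransferase LARGE2 (-3.01, SE 0.24), RAB26 (-4.10, SE 0.36) and COMTD1 (-2.72, SE 0.25). MIR924HG was at least 3.69-fold, KLK1 at least 3.72-fold and TPRG1 at least 3.38-fold lower. All 16 of these genes had limma adjusted p from 0.0426 to 0.0435. They moved the same way in TE8 and HSC-2, which a small p here largely requires, as differences between lines count as spread. For genes given as bounds, the p rests in part on signals not well above background.

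HIF targets rose as a list with DFX across both lines (median 2.05, limma's camera, adjusted p = 9.66e-20), a call lost with an estimated correlation (adjusted p = 0.711). Of its 37 genes 11 rose at the threshold over all genes and 31 adjusted over the list alone. Squamous differentiation (median 1.25; 5 of 31 called, 15 adjusted over the list alone, 14 of them higher), immediate early genes (1.33; 3 of 19, and 9 adjusted over the list alone), ATF4 and amino acid stress (1.27; 1 of 27, and 13 adjusted over the list alone), glycolysis (0.74; 1 of 18, and 6 adjusted over the list alone, 5 of them higher), p53 targets (0.50; 1 of 35, and 7 adjusted over the list alone, 6 of them higher), the unfolded protein response (0.29; 1 of 20, and 2 adjusted over the list alone) and cholesterol synthesis (0.57; 0 of 24, and 2 adjusted over the list alone) rose too. All 13 list calls of this contrast, rises and falls, rest on camera's preset correlation of 0.01 and were lost with an estimated correlation, where each had an adjusted p = 0.711. On 2 residual degrees of freedom that alternative has little power, so the losses do not show that the lists were unchanged. DNA replication (median -0.86; 0 of 33, and 5 adjusted over the list alone), ribosome biogenesis (-0.61; 0 of 26, and 2 adjusted over the list alone), DNA repair (-0.81), mitosis (-1.12) and the respiratory chain (-0.28) fell, the last 3 with 0 genes called and 0 adjusted over the list alone. Against control, the fall of mitosis came from HSC-2 (-2.26), as the TE8 median was 0.15 and not shifted. That TE8 median rests on 1 control array, against which mitosis was raised with cisplatin (0.79) and SP10 (0.76). With DFX against SP10 in TE8 it was -0.61 and below its random lists, though this sets 1 treatment against another. Whether mitosis fell in TE8 with DFX therefore stays open. The respiratory chain was outside the random range in HSC-2 alone, with TE8 just inside it at percentile 4.15. The unfolded protein response was shifted in TE8 alone (0.55, against 0.03 in HSC-2). These differences between the lines were not tested. With spike-in scaling the medians of p53 targets and the unfolded protein response fell below 0, and the latter lost its call (limma's camera, adjusted p = 0.0656). The count of 242 genes became 0 with quantile normalization, with no filter on dim probes, or without either control array, 136 without HSC-2 CDDP, 386 without TE8 CDDP, 1568 without TE8 DFX and 1099 without HSC-2 DFX.

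In TE8, cisplatin was followed by higher interferon genes. Of 24 listed genes 11 were higher by at least 2-fold and 0 lower (median 0.92), such as IFIT3 (1.80), OAS1 (1.68), OASL (1.51) and HERC5 (1.33). ATF4 and amino acid stress genes were higher in 6 of 26 cases (median 0.59), with the pseudokinase TRIB3 (2.09), CHAC1 (1.68) and ATF3 (1.63). Among p53 targets (3 of 35 higher, median 0.30) the stress cytokine GDF15 (2.31), the death receptor FAS (1.09) and CDKN1A (1.04) were higher and MDM2 was at 0.37. Mitosis (2 of 31 higher, NEK2 at 1.50), DNA replication (1 of 33 higher, RRM2 at 1.19), DNA repair (1 of 32 higher, EXO1 at 1.11), ribosome biogenesis (median 0.33), heat shock (0.35), NF-kB and inflammation (4 of 18 higher, 2 lower, IL1B at 1.81), immediate early genes (4 of 19 higher, 1 lower, DUSP5 at 1.35) and squamous differentiation (2 of 28 higher, LCE3D at 1.49) were shifted higher as lists.

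The 8 highest genes in TE8 with cisplatin were SLC2A3 (3.34), CXCR4 (3.18), the long non-coding RNA UCA1 (3.15), TFPI2 (2.94), SNORA79 (2.89), KRT222 (2.78), TNNC1 (2.75) and CCL26 (2.66). The 8 lowest were TRAPPC9 (-5.33), IMMP2L (-5.18), SLC24A3 (-4.36), SORCS2 (-4.36), the cadherin CDH13 (-4.06), CPQ (-4.03), MSRA (-3.76) and GGT5 (-3.73). Histone genes (median -0.30, 1 of 18 lower, H2BC21 at -1.49), basal keratinocyte genes (-0.16, 0 of 15 lower) and EMT (-0.28, 4 of 24 lower and 3 higher) were shifted lower, the last with the matrix metalloproteinases MMP10 (-3.12), MMP1 (-2.15) and MMP13 (-2.10). HIF targets (median -0.04), glycolysis (-0.001), iron uptake and storage (0.01), the unfolded protein response (-0.04), NRF2 targets (0.17), cholesterol synthesis (0.17), the respiratory chain (0.20), metallothioneins and zinc (0.01) and stemness (0.30) were not shifted. NANOG was at least 5.01-fold lower, POU5F1 stood at -1.34 and SOX2 at 1.12.

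Of 17033 genes judged in TE8 with cisplatin 691 were higher and 1061 lower, 351 as bounds, and 50.9% of calls were higher with quantile normalization in place of 39.4%. Of 15494 genes, 205 were at least 2-fold above all 3 other TE8 arrays on the control array and 73 below, against 98 and 120 for TE8 CDDP, 958 and 784 for TE8 DFX and 8 and 31 for TE8 SP10. Fibroblast markers moved with the same groups (median -0.68, 3 of 7 lower). With the SP10 array as the reference, an alternative chosen after seeing the data, 655 genes were higher and 436 lower.

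In HSC-2, cisplatin gave higher squamous differentiation and inflammation genes. Of 31 squamous genes 16 were higher and 0 lower (median 1.05), among them S100A8 (2.51), S100A9 (2.26), SPRR1B (2.36) and SPRR2A (2.14). NF-kB and inflammation genes (4 of 23 higher, median 0.46) included the cytokine IL6 (3.29), the cyclooxygenase PTGS2 (1.49) and CSF2 (1.10). DNA replication was shifted higher with 6 of 33 genes higher (median 0.66), such as the cyclins CCNE2 (1.84) and CCNE1 (1.37) and the ribonucleotide reductase RRM2 (1.52), and so was DNA repair (1 of 32 higher, EXO1 at 1.63). Mitosis genes were lower, 12 of 31 with 0 higher (median -0.77), such as KIF20A (-2.85), AURKA (-1.69), HMMR (-1.65) and CENPE (-1.59). HIF targets were lower in 12 of 36 cases (median -0.81; BNIP3 -2.01, EGLN3 -1.80), and glycolysis in 2 of 17 (median -0.54; PGK1 -1.27, LDHA -1.24). The list of metallothioneins and zinc, which also holds zinc transporters, was lower in 6 of 12 cases (median -1.13; MT1B -1.90, MT1X -1.89, MT1E -1.75).

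Smaller shifts in HSC-2 with cisplatin were higher medians for interferon response (0.30, IRF7 at 1.23), ATF4 and amino acid stress (0.26, PPP1R15A at 1.50) and ribosome biogenesis (0.20). Lower medians were found for immediate early genes (-0.35, 5 of 19 lower, EGR1 at -2.93 and FOS at -2.15), histone genes (-0.47, 5 of 18 lower, H1-5 at -1.88), the unfolded protein response (-0.41, PDIA4 at -0.99), basal keratinocyte genes (-0.45) and EMT (-0.36, LOXL2 at -1.84, VIM at -1.59 and MMP1 at 1.64). Cholesterol synthesis (-0.33, 0 of 24 lower) lay on its random limit, at percentile 2.48, and counts as shifted only barely. The p53 targets (0.06) were not shifted, with 4 of 34 higher and 2 lower, although GDF15 (1.37), BTG2 (1.20) and CDKN1A (1.14) were higher and MDM2 was at 0.06. Iron uptake and storage (-0.09), stemness (-0.26), NRF2 targets (-0.18), the respiratory chain (-0.12) and heat shock (-0.33) were not shifted. The highest genes were IGFBP1 (3.77), IL6 (3.29), IL36G (3.20), KLHDC7B (3.14), CARD18 (2.81), IL24 (2.77), S100A8 (2.51) and OLR1 (2.49), and the lowest PIF1 (-3.97), DHRS2 (-3.75), BBS9 (-3.62), IMMP2L (-3.46), CDH13 (-3.35), HHAT (-3.33), NALF1 (-3.06) and KCNMA1 (-3.03). Of 15494 genes judged 458 were higher and 532 lower, 175 as bounds. Spike-in scaling moved the median of all genes by 0.18 and gave 69.7% of calls higher in place of 46.3%.

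Across both lines, limma called 0 genes higher and 0 lower for cisplatin of 16954 tested (smallest adjusted p = 0.342), with 395 and 527 at an unadjusted p under 0.05. The smallest p values belonged to NBEA (at least 10.56-fold lower), TRAPPC9 (at least 29.68-fold lower) and ULK4 (at least 3.28-fold lower), all bounds because not every cisplatin array was well above background. Their p came from the signals as measured, not from the bounds. On the higher side stood HSD17B2 at 2.09 (SE 0.27), the cytidine deaminase APOBEC3B at 1.93 (SE 0.28) and HECW2-AS1 at 1.80 (SE 0.28). DNA replication (median 0.55, limma's camera, adjusted p = 1.35e-07), DNA repair (0.36), ATF4 and amino acid stress (0.44), squamous differentiation (0.73), interferon response (0.49), NF-kB and inflammation (0.30), p53 targets (0.19) and ribosome biogenesis (0.25) rose as lists, and HIF targets (-0.42), histone genes (-0.44), glycolysis (-0.28) and the unfolded protein response (-0.21) fell. None of the 12 calls held with an estimated correlation, where the adjusted p was 0.713 for glycolysis and for ribosome biogenesis and 0.711 for each of the others. In these lists 0 genes passed over all genes and 0 adjusted over the list alone. The falls of HIF targets, glycolysis and the unfolded protein response lay outside the random range in HSC-2 alone. In TE8, HIF targets (percentile 3.34) and the unfolded protein response (3.36) lay just inside it on the low side, with glycolysis at 8.16. The p53 targets were shifted in TE8 alone, and these differences between the lines were not tested. Left without TE8 DFX, limma called 20 genes lower, and without HSC-2 DFX 17.

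Set against each other across both lines, cisplatin and DFX differed in 220 genes by limma, 70 higher and 150 lower with cisplatin (2265 and 2285 at an unadjusted p under 0.05), which became 2416 and 309 with spike-in scaling. HIF targets were lower with cisplatin than with DFX (median -2.42, limma's camera, adjusted p = 2.18e-20, and 0.711 with an estimated correlation), 13 of 37 at the threshold over all genes and 35 adjusted over the list alone. RORA (-4.37, SE 0.27) and RFPL4AL1 (-4.73, SE 0.29) were lower with cisplatin. CA9 (at least 11.21-fold), PKIB (at least 7.37-fold) and NEBL (at least 13.0-fold) were lower too, as bounds because 1 of the 2 cisplatin arrays was not well above background. The keratinocyte genes KPRP and LCE2C were at least 13.64-fold and 9.92-fold lower and the Notch ligand DLL4 at least 3.61-fold lower. CLXN was higher with cisplatin by 4.11 (SE 0.24), HSD17B8 by 3.23 (SE 0.25), the ubiquitin ligase CBLC by 2.83 (SE 0.25), ARAP3 by 2.75 (SE 0.25) and MNS1 by 2.72 (SE 0.26), with KLK1 at least 8.73-fold, LEF1-AS1 at least 3.97-fold and TPRG1 at least 3.78-fold higher. These 16 genes had limma adjusted p from 0.0365 to 0.0386, taken from the signals as measured also where a bound is given.

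The 15 other list calls of this contrast were also lost with an estimated correlation, each with an adjusted p = 0.711. With the preset, DNA replication was higher with cisplatin than with DFX (median 1.44; 1 of 33 called and 22 adjusted over the list alone), as were DNA repair (1.04; 0 of 32, and 17 adjusted over the list alone), mitosis (1.04), ribosome biogenesis (0.89), interferon response (0.97) and the respiratory chain (0.42). Glycolysis (-0.91; 1 of 18, and 11 adjusted over the list alone, 1 of them higher), immediate early genes (-1.10), ATF4 and amino acid stress (-0.80), squamous differentiation (-1.08; 3 of 31, and 13 adjusted over the list alone, 2 of them higher), cholesterol synthesis (-0.76), the unfolded protein response (-0.60), basal keratinocyte genes (-0.91), EMT (-0.29, and 0.30 with spike-in scaling) and histone genes (-1.39) were lower. Adjusted over the list alone, 15 histone genes were called with 4 of them higher, 10 basal keratinocyte genes with 1 higher and 8 EMT genes with 1 higher. None of these list calls held with an estimated correlation. The 220 genes became 0 with quantile normalization, with no filter, or without any of the 4 control and cisplatin arrays, 2091 without TE8 DFX and 922 without HSC-2 DFX.

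**Figure D1:**
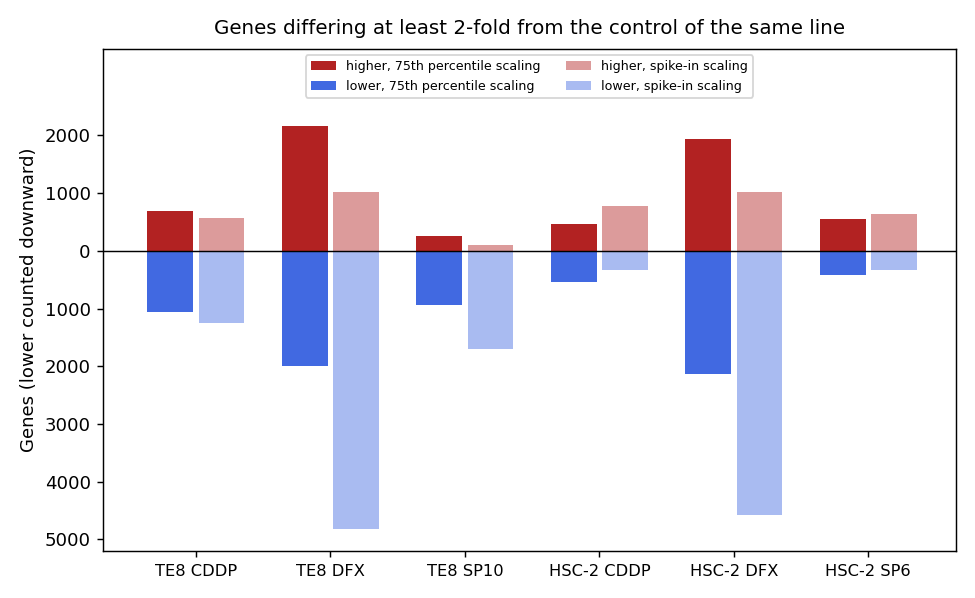
Number of genes at least 2-fold higher (upward bars) or lower (downward bars) than the control of the same line in the 6 comparisons, with 75th percentile scaling (dark) and spike-in scaling (light), 1 array per group. With DFX in TE8 the 2166 higher and 1993 lower genes become 1024 and 4815, and in HSC-2 the 1935 and 2130 become 1022 and 4580.

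SP10 in TE8 gave a smaller response. The highest genes were ECH1 (5.48), a peroxisomal and mitochondrial isomerase measured by a single probe, LCN2 (4.18), the siderophore-binding lipocalin, and SPRR2A (3.35), followed by TMEM200A (2.76), SPRR2E (2.62), MANCR (2.54), STC2 (2.51) and GPAT3 (2.47). ATF4 and amino acid stress genes were higher in 8 of 26 cases (median 0.73), among them TRIB3 (2.33), CHAC1 (2.14) and the cystine transporter SLC7A11 (2.03). Heat shock genes (3 of 16 higher, median 0.70) were led by HSPA6 (1.67) and HSPA1B (1.40), and NRF2 targets (4 of 23 higher, 1 lower, median 0.57) by the aldo-keto reductase AKR1C1 (2.04) and TXNRD1 (1.37). Mitosis (4 of 31 higher, median 0.76, AURKA at 1.20), DNA replication (0.50) and ribosome biogenesis (0.60) were shifted higher, and basal keratinocyte genes (-0.15) lower. Another 4 lists lay just above the upper limit of their random lists. These were iron uptake and storage (0.376 against 0.365, 1 of 25 higher) and DNA repair (0.372 against 0.355). The others were the respiratory chain (0.414 against 0.398) and histone genes (0.414 against 0.395, H1-5 at 1.15).

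HIF targets were not shifted with SP10 (median 0.00, 2 higher and 2 lower of 36), with CA9 at -0.44, NDRG1 at 0.27 and VEGFA at 0.21. TFRC stood at 0.40, FTH1 at 0.08 and CDKN1A at 0.19. Glycolysis (0.24), p53 targets (0.19), stemness (0.22), the unfolded protein response (0.31), metallothioneins and zinc (0.31), interferon response (0.18), NF-kB and inflammation (0.12, IL1B at 2.03), immediate early genes (0.33), cholesterol synthesis (0.22), squamous differentiation (-0.02) and EMT (0.09) were not shifted. The lowest genes were S100A3 (-2.86), CD86 (-2.64), TMEM190 (-2.60), INMT (-2.51), CASC15 (-2.39), SPAG17 (-2.35), NALF1-IT1 (-2.33) and MST1 (-2.33). NANOG was at least 3.98-fold lower, POU5F1 stood at -1.08 and SOX2 at 1.35. Fibroblast markers were shifted lower (median -0.65, 1 of 6 lower), and the SP10 array itself held 8 genes at least 2-fold above and 31 below all other TE8 arrays of 15494. Of 16861 genes judged 253 were higher and 939 lower, 186 as bounds, so that 21.2% of calls were higher, against 34.8% with quantile normalization and 6.0% with spike-in scaling, which moved the median of all genes by -0.26. With the cisplatin array as the reference, chosen after seeing the data, 436 genes were higher and 655 lower.

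SP6 in HSC-2 was followed by higher squamous differentiation genes, 21 of 31 by at least 2-fold and 0 lower (median 2.35), with SPRR2A (4.48), KRT6B (3.92), SPRR1A (3.87) and SPRR1B (3.79) at the top. NF-kB and inflammation genes were higher in 14 of 23 cases (median 1.48), such as the growth factor CSF3 (4.74), the chemokine CXCL8 (2.92), PTGS2 (2.90) and CSF2 (2.62). The epidermal cytokine IL36G (5.54) and the elastase inhibitor PI3 (4.71) were among the highest, with SPRR2E (4.51), SPRR2F (4.50), SPRR2C (4.35) and S100A12 (4.08). NRF2 targets (5 of 23 higher, median 0.54, AKR1C1 at 1.56), p53 targets (5 of 35 higher, 1 lower, CDKN1A at 1.35), ATF4 and amino acid stress (4 of 26 higher, ATF3 at 1.38), immediate early genes (3 of 19 higher, NR4A2 at 1.84), EMT (4 of 22 higher, 1 lower, MMP1 at 2.07), cholesterol synthesis (1 of 24 higher, SC5D at 1.27) and basal keratinocyte genes (median 0.15) were shifted higher. Mitosis genes were lower, 24 of 31 with 0 higher (median -1.25; KIF20A -2.19, DLGAP5 -1.66), and so were DNA replication (3 of 33 lower, median -0.56), DNA repair (-0.42), ribosome biogenesis (-0.28) and interferon response (6 of 22 lower, median -0.59, IFIT1 at -1.98).

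HIF targets were not shifted with SP6 (median 0.05), with 3 of 35 higher (KDM7A at 2.25, RORA at 1.08, CA12 at 1.03), NDRG1 at 0.41 and VEGFA at 0.88. Iron uptake and storage (0.10; TFRC 0.18, FTH1 0.06), glycolysis (-0.22), stemness (-0.20; POU5F1 -0.37, SOX2 -0.70), the unfolded protein response (-0.03), metallothioneins and zinc (-0.14), the respiratory chain (-0.20), heat shock (-0.16) and histone genes (-0.07) were not shifted. The lowest genes were PADI3 (-3.35), CCN5 (-3.16), CTSZ (-2.89), SNAR-G1 (-2.71), SNORA28 (-2.68), APLN (-2.63), PIF1 (-2.60) and CCDC71 (-2.52). Of 15288 genes judged 551 were higher and 417 lower, 175 as bounds. In HSC-2 too few fibroblast markers were measured for a list median, and leukocyte and endothelial markers were not shifted in any of the 6 comparisons, with medians from -0.45 (TE8 SP10) to 0.97 (HSC-2 DFX).

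The chelators were given at different doses and in different units, and SP6 and SP10 each in a single line, so that their values stand side by side without a match of dose. In TE8, DFX exceeded SP10 by at least 2-fold in 2044 genes and was below it in 1702 of 16796, led by LCE3D (6.25), LCE3E (5.84), FLG (5.78), SPINK1 (5.76) and CRCT1 (5.64), and by ECH1 (-5.57), KRT15 (-5.25), H1-1 (-4.18) and HPDL (-4.02). HIF targets were higher with DFX than with SP10 in 30 of 37 cases (median 2.18, CA9 at 5.29) and squamous differentiation in 20 of 29 with 2 lower (2.27), and NF-kB and inflammation genes in 10 of 21 with 3 lower (0.95). In HSC-2, DFX exceeded SP6 in 1642 genes and was below it in 1561 of 15670, with ZP1 (5.79), IGFBP3 (5.09), CCN5 (4.87), PSG8 (4.69) and DRD5 (4.63) at the top. ALDH3A1 (-7.05), CYP1A1 (-6.60), DAPL1 (-5.43), LIF (-5.39) and the acute phase protein SAA1 (-4.61) were at the bottom. LIF has another measured probe that went the opposite way by at least 2-fold. HIF targets were higher with DFX than with SP6 in 30 of 37 cases (median 1.73), while NF-kB and inflammation genes were lower in 12 of 23 (-1.10, CXCL1 at -4.57) and squamous differentiation was not shifted, with 4 higher and 11 lower of 31 (-0.25). Mitosis was lower with DFX than with the other chelator in both lines (median -0.61 in TE8, -1.14 in HSC-2). With spike-in scaling 30.4% (TE8) and 12.6% (HSC-2) of calls were higher in place of 54.6% and 51.3%, and the median of all genes moved by -0.31 and -0.59.

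Across both lines, limma called 0 genes higher and 0 lower for the 4 chelator arrays against the 2 controls of 17081 tested (smallest adjusted p = 0.215), with 380 and 326 at an unadjusted p under 0.05. The smallest p on the higher side belonged to IL13RA2 (at least 4.02-fold higher), S100P at 2.87 (SE 0.39) and TNFRSF9 (at least 3.46-fold higher), and on the lower side to MYO3B (at least 1.76-fold lower), TDRD10 (at least 3.05-fold lower) and SPACA6 at -1.45 (SE 0.27). Where a bound is given, the p came from the signals as measured. As lists, ATF4 and amino acid stress (median 1.03, limma's camera, adjusted p = 2.80e-11), HIF targets (1.10), squamous differentiation (1.27), NF-kB and inflammation (0.69), immediate early genes (0.84), glycolysis (0.41), cholesterol synthesis (0.44), NRF2 targets (0.34; 2 of 23 adjusted over the list alone), p53 targets (0.29) and the unfolded protein response (0.20) rose, and mitosis (-0.70), DNA replication (-0.47), DNA repair (-0.42) and interferon response (-0.55) fell. All 14 calls were lost with an estimated correlation, each with an adjusted p = 0.711. These class medians hide differences between the arrays. HIF targets were shifted with DFX (2.27 and 1.78) and not with SP10 (0.00) or SP6 (0.05). In TE8 with SP10, mitosis (0.76), DNA replication (0.50) and DNA repair (0.37) were shifted higher. In TE8 with DFX, mitosis (0.15) was not shifted and interferon response (0.39) was shifted higher. Against these controls the falls of mitosis and interferon response thus came from HSC-2, and the TE8 side rests on 1 control array. The p53 and unfolded protein response medians fell below 0 with spike-in scaling, and the latter lost its call (limma's camera, adjusted p = 0.0619).

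The 2 lines were compared gene by gene over 13853 genes measured in every comparison. Genes are not independent replicates, so r describes these arrays. The log2 differences of DFX correlated between TE8 and HSC-2 with r = 0.518, those of cisplatin with r = 0.310, and SP10 with SP6 at r = -0.076. Calls were counted over all genes judged in both lines, bounds included. With DFX, 860 of 15267 genes were higher in TE8 and in HSC-2 and 600 lower, against 220.0 and 218.6 for independent lists. With cisplatin, 100 of 15064 were higher and 134 lower, against 13.5 and 21.8. Another 149 genes with DFX and 18 with cisplatin were called in opposite directions. Comparisons within a line share their control array, and unchanged arrays simulated against a shared control gave r = 0.499 and a covariance of 0.118. In TE8, cisplatin and SP10 had r = 0.652 and a covariance of 0.178, cisplatin and DFX 0.404 and 0.197, and DFX and SP10 0.385 and 0.179. In HSC-2, DFX and SP6 had r = 0.513 and a covariance of 0.244, cisplatin and SP6 0.345 and 0.085, and cisplatin and DFX 0.245 and 0.116. Cisplatin and SP10 shared 541 lower genes in TE8 of 16754 judged in both, against 59.5 for independent lists. Lists with a shared control are not independent, so 59.5 is not the count for unchanged arrays, which was not simulated. With 1 control array per line the controls cannot be split, so part of the excess may come from the shared control.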

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

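The tests weighing mitosis, other than the planned quantile normalization, were chosen after the result was seen. With 1 array per group the differences between lines were not tested, and each stands here because TE8 and HSC-2 moved in opposite directions under the same treatment.

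Mitosis genes stood apart by 1.57 (log2, TE8 minus HSC-2) with cisplatin: their median was 0.79 in TE8 and -0.77 in HSC-2, both outside the range of random lists. A scaling that depends on signal is argued against only by the size of the median, which quantile normalization left at 0.67 (0.665) in TE8. It was still above its random lists, but these have the same signal and move nearly alike, so that place tests little. That the TE8 control culture or its array stands apart stays open: without that array, cisplatin against SP10 in TE8 gave a median of 0.01 (0.006) at percentile 97.3, just inside the central 95% of random lists. The SP10 array had a raised mitosis median against control as well (0.76), so the control and an effect common to both treatments cannot be told apart, and other pairs without a control array (0.56 for TE8 CDDP against DFX, -0.61 for TE8 DFX against SP10, 0.43 for HSC-2 CDDP against SP6) each set a treatment against another and leave this open. A difference between the lines in how division responds to cisplatin is a biological explanation that stays open and was not tested.

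Immediate early genes differed by 0.74 (0.737) between the lines with cisplatin, with medians of 0.39 in TE8 and -0.35 in HSC-2. IL36G, an epidermal cytokine, differed by -4.71 with cisplatin, at -1.51 in TE8 and 3.20 in HSC-2. Interferon response genes differed by 2.01 with DFX, with medians of 0.39 in TE8 (-0.17 with spike-in scaling) and -1.62 in HSC-2.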

How the results depend on the processing

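Only the tests with another reference array in TE8 were chosen after the result was seen. Limits come from 1 array per group and from dim probes, as only 46.9% to 55.3% of probes per array were well above background. No called direction of a named gene turned round in the settings in which genes were followed (5 within lines, and across lines all but leaving out an array), but counts moved, and so did the balance of higher and lower genes: 691 and 1061 in TE8 CDDP became 971 and 938 with quantile normalization, and 2166 and 1993 in TE8 DFX became 1024 and 4815 with spike-in scaling. With spike-in scaling some list medians changed sign while keeping their place against random lists, as the report states. The cause was not tested, except that normexp with its offset draws dim probes together and that a filter changes which genes are judged or tested. With normexp the 6 comparisons with control gave 650 (TE8 CDDP), 2580 (TE8 DFX), 447 (TE8 SP10), 400 (HSC-2 CDDP), 2682 (HSC-2 DFX) and 424 (HSC-2 SP6) genes, and DFX against SP10 and SP6 gave 2343 and 1820. With no filter on dim probes TE8 CDDP gave 2858, TE8 SP10 2199, HSC-2 CDDP 2148 and HSC-2 SP6 2006. Spike-in scaling gave 1807 for TE8 SP10 and 5386 for DFX against SP6. TE8 CDDP against the SP10 array gave 1091. DFX across lines (242 genes) gave 0 with quantile normalization, 1459 with spike-in scaling, 1068 with normexp, 378 with the mean of probes, 1248 with the filter on all arrays, 0 with no filter, 1163 with a variance trend and 0 to 1568 leaving out 1 array. Cisplatin against DFX (220 genes) gave 0 with quantile normalization, 2725 with spike-in scaling, 1373 with normexp, 343 with the mean of probes, 1533 with the filter on all arrays, 0 with no filter, 1357 with a variance trend and 0 to 2091 leaving out 1 array. Cisplatin against control gave 0 in every other setting and 0 to 20 leaving out 1 array, 20 without TE8 DFX and 17 without HSC-2 DFX, and the chelator class gave 0 in all settings run. Where a fit lacks 1 array of a line, the remaining array is taken to vary like the other groups. The 55 list calls across lines became 0 with an estimated correlation and 0 with fry (smallest adjusted p = 0.164), and were 52 to 61 under the scalings, background correction, filters and variance trend. With an estimated correlation the few residual degrees of freedom leave little power, so these losses do not show unchanged lists. Within lines 941 of 980 list results stayed on their side of the random range, 23 left it and 16 entered the shifted side. All 75 correlations stayed within 0.1. Spike-in scaling and scaling on the median shift all genes of an array by the same amount, so they cannot change a correlation. They also move a list and its random lists nearly alike, so the counts above test little under these settings. Named genes within lines moved by at least their spot error in 1166 of 4665 results and across lines lost their call in 74 of 328.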

Other observations

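The tests of very long genes and of the DFX shift were chosen after the results were seen, although spike-in scaling itself was planned, and the gene list of the first pattern was written from background knowledge after the pattern was noticed.

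Several of the lowest genes with cisplatin in either line (TRAPPC9, IMMP2L, CDH13, CPQ, MSRA, BBS9) are known, from background knowledge, as very long genes. A list of 114 other very long genes, 113 of them on the arrays, was therefore tested. Its median was -0.65 with cisplatin in TE8, where 28 of 77 judged genes (36.4%) were at least 2-fold lower against 6.23% of all genes. In HSC-2 it was -0.58, with 18 of 66 (27.3%) lower against 3.43% of all genes. With the chelators the list stayed inside its random lists: -0.12 and 0.001 with DFX, 0.02 with SP10 and -0.02 with SP6.

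Technical explanations were set against a drug effect on very long genes. Dim signal is argued against, since members in the upper part of the signal range (above the median) stayed below their random lists in both lines (at percentile 0.00 in TE8 with 20 genes, and 2.26 in HSC-2 with 17), although the HSC-2 value is borderline (-0.257 against a random limit of -0.253). The control arrays are argued against by a median of -0.54 for cisplatin against SP10 in TE8 and -0.53 (-0.525) against SP6 in HSC-2. The choice among these scalings did not remove the low medians, with none above -0.37 (-0.372) under any of the 4 other settings in either line. The place of the list below its random lists tests little here. Scaling on spike-in probes or on the median moves both alike, and quantile normalization moves genes of like signal nearly alike. What stays open is a hypothesis that cisplatin, and not the chelators at these doses (lowest median -0.121), may lower transcripts of very long genes, or of genes that share another property such as a short transcript half-life, which was not tested.

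Under spike-in scaling the median of all genes moved by -0.56 in TE8 and -0.50 (-0.504) in HSC-2 with DFX, while it moved by -0.26 to 0.18 in the other 4 comparisons. Ordinary spread of the spike-in signal cannot be told apart from an effect of DFX, because the 2 untreated controls differ by 0.515 on the same scale, though between lines. Less target RNA beside the spike-in mix on the DFX arrays (mean shift -0.532) cannot be told apart either from less messenger RNA per cell or a handling difference, since the labels give 1 to 5 ug of total RNA for labelling of every sample, with no amount or cell number per array.

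Of probes without a gene name, 1770 were at least 2-fold lower and 356 higher with cisplatin in TE8, 1844 and 146 with SP10, and 1878 and 795 with DFX. In HSC-2 the lower and higher counts were 376 and 210 with cisplatin, 587 and 1397 with DFX, and 315 and 177 with SP6. Without the TE8 control array, cisplatin against SP10 gave 183 lower and 441 higher of 9613. Called genes rarely had another measured probe going at least 2-fold the other way, with 9 of 838 in HSC-2 with DFX.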
